A study of Homo sapiens with 12 samples.

How the data were processed

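The series measured ribosome-protected fragments in 12 human libraries, 8 from HEK293T cells exposed to sodium arsenite and 4 from H9 embryonic stem cells. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with Illumina's TruSeq small RNA kit, which ligates adapters to both ends of each fragment. Per the submitters' processing notes, cutadapt and STAR 2.5.2b were used with the human genome build hg19. The counter, its strand setting, the annotation release and the removal of ribosomal RNA reads are not given in the sources used here. The deposited values are whole-number counts of reads per coding sequence, not normalized, with 1 RefSeq transcript accession per row and summary rows for reads outside coding sequences, ambiguous reads and reads with more than 1 alignment. The mRNA-seq of the study was not used here, so counts follow both mRNA level and translation, and no translational efficiency was computed. Without the strand setting, reads of overlapping genes on opposite strands cannot be told apart.

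The rows that name no gene stayed out of library sizes and tests. They held 87.5 to 89.5% of all rows' counts in HEK293T and 96.2 to 96.5% in H9, mostly alignments of reads with more than 1 place, so genes with near-identical copies are undercounted. Of 19305 accessions, 18888 were named through NCBI RefSeq's table of the assembly GRCh38.p14, used for names only since the files use hg19, so no coordinates are given, and 417 kept their accession. 7 symbols had 2 accessions, which stayed separate. Coding reads per library ran from 4331459 to 5775177 in HEK293T and from 937990 to 1878700 in H9, and 3 counts, the limit that a count of 0 allows, stand for 0.519 to 3.2 CPM. Intervals of single libraries and ratios are 95% Poisson or exact binomial intervals and cover counting error only, since fragments carried no molecular identifiers.

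Groups came from the sample titles, as did the set numbers. Before any test, each pair of libraries was compared by a chi-square of its counts over genes with at least 20 reads in the pair. On simulated data this gave 1.01 per degree of freedom for 1 library split at random and 5.8 for 2 libraries with added dispersion. The set numbers are 2 per comparison, and the labels do not say that a number marks a shared culture or day, so they were not taken to pair the siRNA groups.

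Counts were tested in R 4.3.3 with edgeR 4.0.16, through filterByExpr, TMM scaling, estimateDisp, a robust glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 8 HEK293T libraries shared 1 fit with 4 residual degrees of freedom, and the 4 H9 libraries had their own with 2, so both members of each near-identical pair entered as samples. Means and SDs of CPM per group use library sizes scaled by TMM, while CPM of single libraries and their ratios use the total of coding reads. Standard errors are the size of the log2 fold change over the square root of the F statistic. Of 24 gene lists, those with at least 3 tested members, 23 in HEK293T and 20 in H9, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. The list of 13 mitochondrially encoded genes was not analysed here. Older symbols were updated through RefSeq synonyms, a step corrected after results of the lists had been seen, which changed the members of the histone and ribosomal protein lists. Tested on simulated counts with 200 genes changed 2-fold, the fit recovered 95.5% of them in the CBP80-labelled comparison (11711 genes), 96.5% in the eIF4E-labelled comparison (11734 genes), 91.5% in H9 (9756 genes) and 97% with runs summed (12347 genes). Of its calls 6.37, 3.02, 5.67 and 5.37% were false, in that order. The simulated libraries were drawn independently at a constant dispersion of 0.01, with no near-identical pairs and no difference between sets. The data held both, so these rates check the code and do not carry over to the fits of the data.

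The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names EIF2A in every library. It then takes, per comparison, the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap and whose mean is at least 20 CPM, or 5 genes of smallest p each way as values where fewer than 5 pass. Per list it takes at most 4 members past the threshold, or 2 as values, and it adds NCBP1, EIF4E, HSPA5, SRC and ATF4. Some genes that the rule takes are not reported here. The fit with both runs of a library summed (4 libraries, 2 residual degrees of freedom) and the description of the H9 sets were added after the data were seen. The alternatives were RLE scaling, library sizes alone, leaving out the 20 most abundant genes, no count filter, a mean count of at least 50, DESeq2 1.42.0, edgeR's legacy option, leaving out each library, the set number as a block, the 4 libraries of a comparison alone and all 12 libraries in 1 fit.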

Results

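Ribosome profiling sequences the short mRNA fragments that ribosomes shield from nuclease, so the number of fragments over a coding sequence follows how many ribosomes were translating it. The series compared such fragments with and without knockdown of eIF2A, a protein that can deliver initiator tRNA to the ribosome, on mRNAs held by each of the cell's cap-binding proteins. These are CBP80, the large subunit of the nuclear cap-binding complex, and eIF4E, the cap-binding protein of the cytoplasm. 8 libraries came from HEK293T, a human embryonic kidney cell line, exposed to sodium arsenite, an oxidative stressor that slows translation. They form 4 groups of 2 by immunoprecipitation (IP) of CBP80 or eIF4E and by control or eIF2A siRNA. 4 libraries came from H9, a human embryonic stem cell line, 2 labelled control shRNA and 2 labelled eIF2A shRNA, with no IP. Each group held 1 library of set 1 and 1 of set 2. The HEK293T libraries held 4331459 to 5775177 reads in coding sequences and the H9 libraries 937990 to 1878700. The labels do not say that the sets were separate cultures, so p-values measure the spread between these libraries, which may be technical.

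The libraries labelled CBP80 IP and eIF4E IP could hardly be told apart by their counts over all genes together. For each siRNA and set, the CBP80 and eIF4E libraries differed by no more than about the sampling noise of their counts. Their chi-square per degree of freedom over genes was 1.01 to 1.03 in the 4 pairs (p = 0.0192 to 0.268), where 1 is sampling noise. Libraries of 1 group from different sets lay at 3.95 to 5.52. A sum over genes can miss single ones. TUSC3 averaged 25.3 CPM with CBP80 and 38.7 CPM with eIF4E labels in control siRNA. With the eIF2A siRNA label it averaged 24.4 and 45.3 CPM. It passed no threshold in the edgeR fit of 8 libraries, whose error held the spread between sets and which could hardly call such a gene. With each pair as a block, fits of 4 libraries called 2 genes in control siRNA and 4 with the eIF2A siRNA label. In H9, the libraries labelled control and eIF2A shRNA lay at 1.04 and 1.07 within a set, slightly above sampling noise (chi-square p = 0.00209 and 5.88e-07), and pairs of different sets lay at 2.67 to 3.31. Over all genes the HEK293T data therefore held 4 clearly distinguishable libraries. Below, the 2 members of each such pair are called runs of 1 library, which the labels do not state. The edgeR fits of 8 and of 4 libraries nonetheless took each library as a sample, so the HEK293T p-values, those of gene lists included, rest on more samples than could be told apart and the H9 p-values on 2 near-identical pairs. For HEK293T, a fit that counts each HEK293T library once stands beside them.

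**Figure D1:**
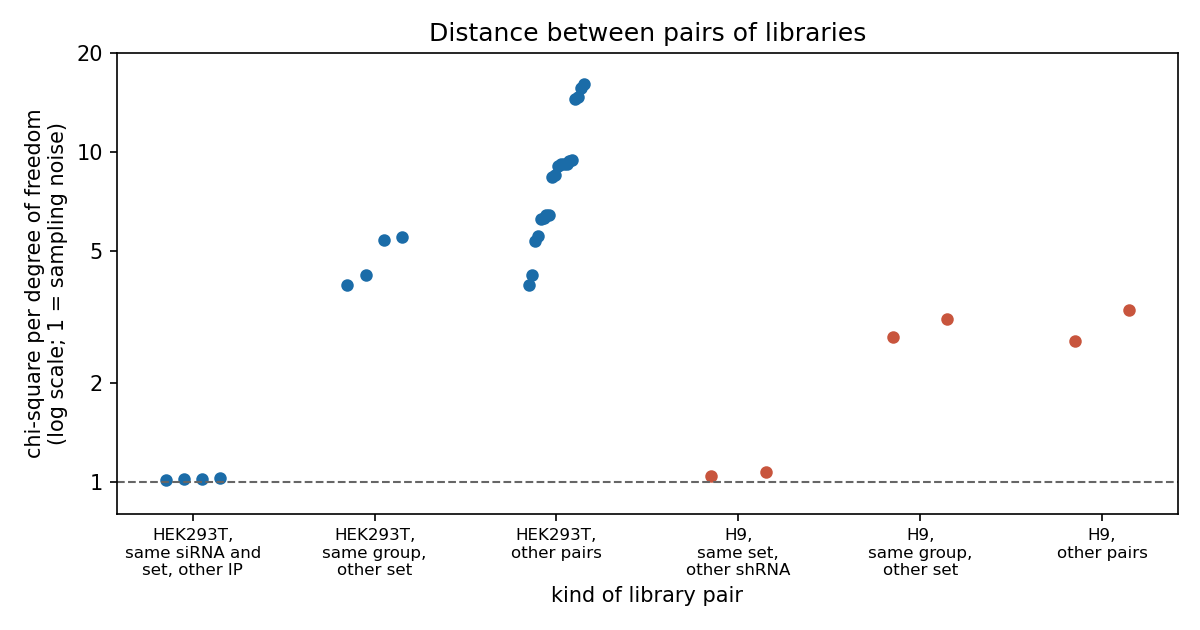
Each point is a pair of libraries from the same cell line, placed by the chi-square per degree of freedom between their counts (log axis, dashed line at 1 for sampling noise) and grouped on the horizontal axis by what their labels share. The 4 HEK293T pairs that differ in the IP label alone lie at 1.01 to 1.03 and the 2 H9 pairs that differ in the shRNA label alone at 1.04 and 1.07, while all other pairs lie at 2.67 or above.

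EIF2A itself (NM_032025 in the files) was not lower in every library labelled as a knockdown. In set 2 of HEK293T, with both runs of a library summed, the library labelled eIF2A siRNA held 46.7 CPM (its count per 1000000 coding reads) against 83.5 in control, a ratio of 0.559 (95% interval 0.5 to 0.626). In set 1 the library labelled eIF2A siRNA held 96 CPM against 83.2 in control, a ratio of 1.15 (1.05 to 1.26). These ratios use total coding reads. With TMM scaling and runs summed, the set 1 library lay 0.06 on the log2 scale above the controls of both sets. It was therefore not lower, but a rise depends on the scaling. Across sets the fitted change was therefore within the spread between libraries. In the CBP80-labelled libraries it was -0.34 ± 0.37 on the log2 scale (SE, edgeR adjusted p = 0.64), from 84.5 ± 0.498 CPM in control to 66.9 ± 30.3 CPM with the eIF2A siRNA label (SD, n = 2). In the eIF4E-labelled libraries it was -0.32 ± 0.37 (edgeR adjusted p = 0.657). Leaving out the set 2 library labelled eIF2A siRNA turned these values to 0.07 and 0.08, while leaving out that of set 1 gave -0.89 and -0.86, and -0.88 with runs summed (edgeR adjusted p = 0.00023). In H9, no difference in EIF2A between the shRNA labels of a set was detectable at this depth, with ratios of eIF2A shRNA over control of 1.07 (0.864 to 1.32) in set 1 and 1.12 (0.802 to 1.56) in set 2. The fitted H9 change was 0.16 ± 0.28 (edgeR adjusted p = 1). The intervals cover counting error only. Since EIF2A was not lower in set 1, each direction below is one between libraries labelled eIF2A siRNA and control. It is not one between cells with shown loss of eIF2A.

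**Figure D2:**
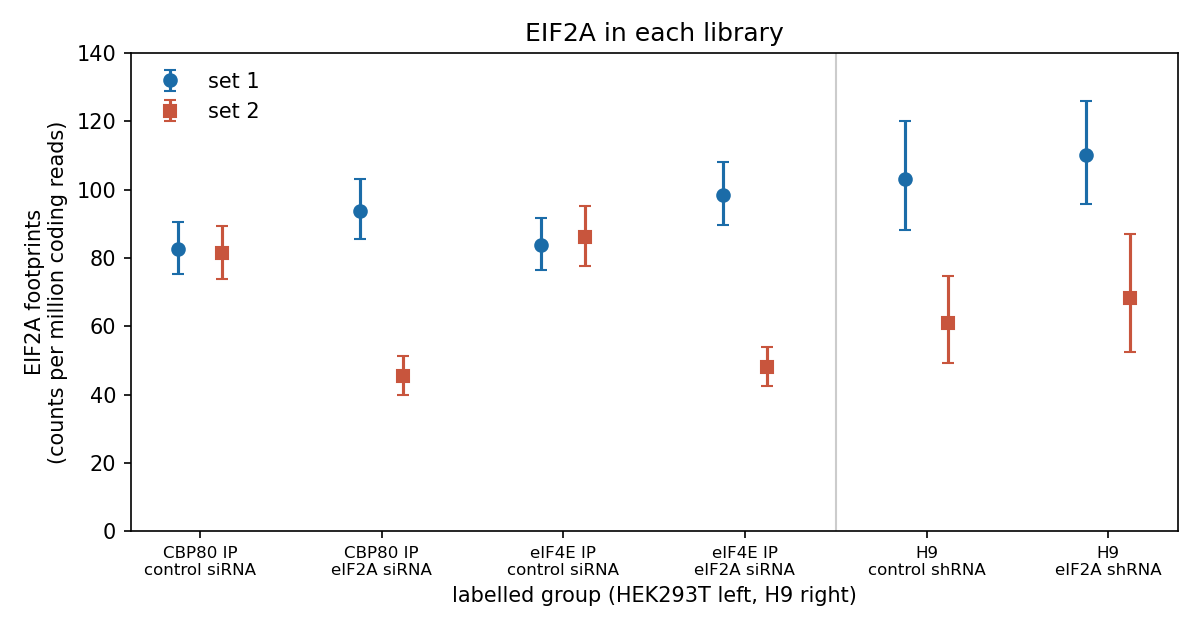
EIF2A footprints in each of the 12 libraries, in CPM (vertical axis), by labelled group (horizontal axis); circles are set 1, squares set 2, and bars are 95% Poisson intervals for counting error. Only the set 2 libraries labelled eIF2A siRNA, at 45.3 and 48 CPM, lie below their HEK293T controls, and in H9 both set 2 libraries, at 60.9 and 68.2 CPM, lie below both set 1 libraries.

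In arsenite-treated HEK293T, footprints on genes of endoplasmic reticulum (ER) chaperones, cholesterol synthesis, histones and the respiratory chain stood lower in libraries labelled eIF2A siRNA at a preset correlation between genes. With an estimated correlation none of these lists was called, at adjusted p = 0.164, 0.164, 0.346 and 0.718 in that order. In the CBP80-labelled libraries the largest falls among genes averaging at least 20 CPM were DPM3 (NM_018973), a subunit of the enzyme that makes dolichol-phosphate mannose (-1.22 ± 0.16 on the log2 scale, SE, edgeR adjusted p = 0.0027), and TSC22D3 (NM_198057), a glucocorticoid-induced leucine zipper protein (-1.12 ± 0.14). DPM3 went from 74.9 ± 3.84 to 32.2 ± 0.00963 CPM and TSC22D3 from 231.3 ± 14.1 to 106.8 ± 22.4 CPM (SD, n = 2). DPM2, a partner of DPM3, fell by 0.96 on the log2 scale and PIGL, an enzyme of glycosylphosphatidylinositol (GPI) anchor synthesis, fell by 0.9. The mitochondrial protein CHCHD2, the secreted growth factor MYDGF and the endoplasmic reticulum protein SUMF2 each fell by 0.99. RPL14, a protein of the large ribosomal subunit, and IGFBP5, a secreted binding protein of insulin-like growth factors, each fell by 0.95. LDOC1 fell by 0.91, the ER chaperone HYOU1 by 0.88 and the glucose-6-phosphate transporter SLC37A4 by 0.87. All of these had edgeR adjusted p between 0.0027 and 0.025.

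The largest rise among genes averaging at least 20 CPM was ATN1 (NM_001007026), a transcriptional corepressor, from 78 ± 5.16 to 165.9 ± 0.202 CPM (1.09 ± 0.11 on the log2 scale, edgeR adjusted p = 0.00088). The chromatin remodeller CHD2 rose by 1.01, the matrix glycoprotein EMILIN2 by 0.97, the deubiquitinase USP25 by 0.92 and NETO2, an auxiliary subunit of kainate receptors, by 0.91. The N-myristoyltransferase NMT2 and the kinase MAPKAPK5 each rose by 0.88, and the sorting nexin SNX6 and the receptor tyrosine kinase FGFR2 by 0.86. REV3L, the catalytic subunit of DNA polymerase zeta, rose by 0.85, GTF3A, the transcription factor of 5S rRNA genes, by 0.82 and RC3H2, an RNA-binding ubiquitin ligase, by 0.81. These rises had edgeR adjusted p from 0.00088 to 0.04. Of the other genes fixed in advance, NCBP1, which encodes CBP80, was at 0.18 ± 0.12 (edgeR adjusted p = 0.398), ATF4 at -0.35 ± 0.13 (0.132) and SRC at 0.16 ± 0.25 (0.733). EIF4E, in the files as NM_001331017, had 7.58 CPM in control and was at 0.04 ± 0.25 (0.935).

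In all, 501 of 11778 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 197 higher and 304 lower with the eIF2A siRNA label. This fit held both runs of each library as separate samples, so its residual spread counts the same libraries more than once. With the runs of a library summed and each library counted once, a comparison added after the data were seen, 1492 of 12331 genes passed, 736 higher and 756 lower. They included 486 of the 501 and all 24 named genes. That count was 78 without the set 2 control, 293 without the library labelled eIF2A siRNA, set 1, and 910 without the set 1 control. With library sizes alone it was 979, 705 higher and 274 lower, with no count filter 633 and in DESeq2 682. The rise from 501 to 1492 does not show stronger evidence. The summed fit leans mostly on a spread shared across genes, with a median of 86.4 prior degrees of freedom against 11.5 in the fit of 8 libraries. Across the 6625 genes above 20 CPM, the change in set 1 correlated with that in set 2 at r = 0.77, across genes, which are not independent replicates. Single libraries decided much of the count: 3 genes passed without the CBP80-labelled control of set 2, 8 without the CBP80-labelled eIF2A siRNA library of set 1, 326 without the set 1 control and 733 without the eIF2A siRNA library of set 2. Scaling by library size alone gave 291 genes, 157 higher and 134 lower, and fitting the 4 CBP80-labelled libraries alone gave 852. The libraries labelled eIF2A siRNA also held a larger share of uniquely placed reads outside coding sequences, 51% against 40% in set 1 and 42.3% against 35.2% in set 2.

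ER chaperones and the unfolded protein response formed 1 of 8 lists, out of 23 fixed in advance that had at least 3 tested members, to stand lower than other genes in that comparison. Of its 20 tested members 8 fell and none rose, 10 when adjusted over the list alone. XBP1, the transcription factor of this response, fell by 0.71, and the disulfide isomerases PDIA6 and PDIA4 fell by 0.61 and 0.59. HSPA5, the main ER chaperone, was at -0.53 ± 0.13 (edgeR adjusted p = 0.035). The list's camera adjusted p was 6.73e-10, and adjusted p = 0.164 with an estimated correlation. Cholesterol synthesis genes also stood lower, with 6 of 23 fallen and 13 when adjusted over the list alone. They included CYP51A1 (-0.72), DHCR7 (-0.68), SQLE (-0.61) and HMGCS1 (-0.51), which encode enzymes of that pathway (camera adjusted p = 1.86e-08, and adjusted p = 0.164 with an estimated correlation). Both lists were lower in the libraries that held the larger share of reads outside coding sequences given above, as were those that follow. Whether the changes followed the length of the coding sequence, which is short in histone, ribosomal protein and many respiratory chain genes, was not tested for any list or named gene, since no coding lengths were used here.

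Replication-dependent histone genes stood lower, with 12 of 44 tested members fallen and none risen, and 26 fallen when adjusted over the list alone. H4C3 went from 1727 ± 152 to 1025 ± 114 CPM (-0.75 ± 0.13, edgeR adjusted p = 0.011), and H4C16, H2AC20 and H4C4 fell by 0.59, 0.52 and 0.5 (camera adjusted p = 4.92e-13, and adjusted p = 0.346 with an estimated correlation). Histone genes are near copies of each other, so which member a read came from is uncertain. Nuclear-encoded subunits of oxidative phosphorylation stood lower by a median of -0.3, with 5 of 61 fallen, NDUFA13 (-0.62), NDUFB9 (-0.48), NDUFB8 (-0.47) and ATP5PB (-0.46) among them, and 20 fallen and 1 risen when adjusted over the list alone. That list had a camera adjusted p of 2.05e-08, and adjusted p = 0.718 with an estimated correlation. Glycolysis had 4 of 16 fallen, the same number as when adjusted over the list alone, with ENO2 at -0.63, TPI1 at -0.52, HK2 at -0.46 and GPI at -0.42 (camera adjusted p = 0.00147, and adjusted p = 0.346 with an estimated correlation).

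Targets of the integrated stress response, the program that ATF4 drives, had 4 of 27 fallen, and 11 fallen and 1 risen when adjusted over the list alone. ATF3 fell by 0.76, the serine and glycine enzymes SHMT2 and PSAT1 by 0.69 and 0.46, and the cystine transporter SLC7A11 by 0.56 (camera adjusted p = 0.000182, and adjusted p = 0.349 with an estimated correlation). Cytosolic ribosomal proteins stood lower by a median of -0.15 over 72 members, of which 2 fell, RPL14 among them, and RPL17, at 3.76 CPM in control, rose. Adjusted over the list alone, 10 fell and 2 rose (camera adjusted p = 0.00143, and adjusted p = 0.761 with an estimated correlation). Ribosomal protein genes have many pseudogene copies, so their counts are uncertain. DNA replication genes stood lower by a median of -0.18 over 35 members. CDC45, a helicase subunit, fell by 0.54 and CCNE1, the cyclin of S-phase entry, rose by 0.67, and adjusted over the list alone 5 fell and 2 rose (camera adjusted p = 0.00868, and adjusted p = 0.442 with an estimated correlation).

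**Figure D3:**
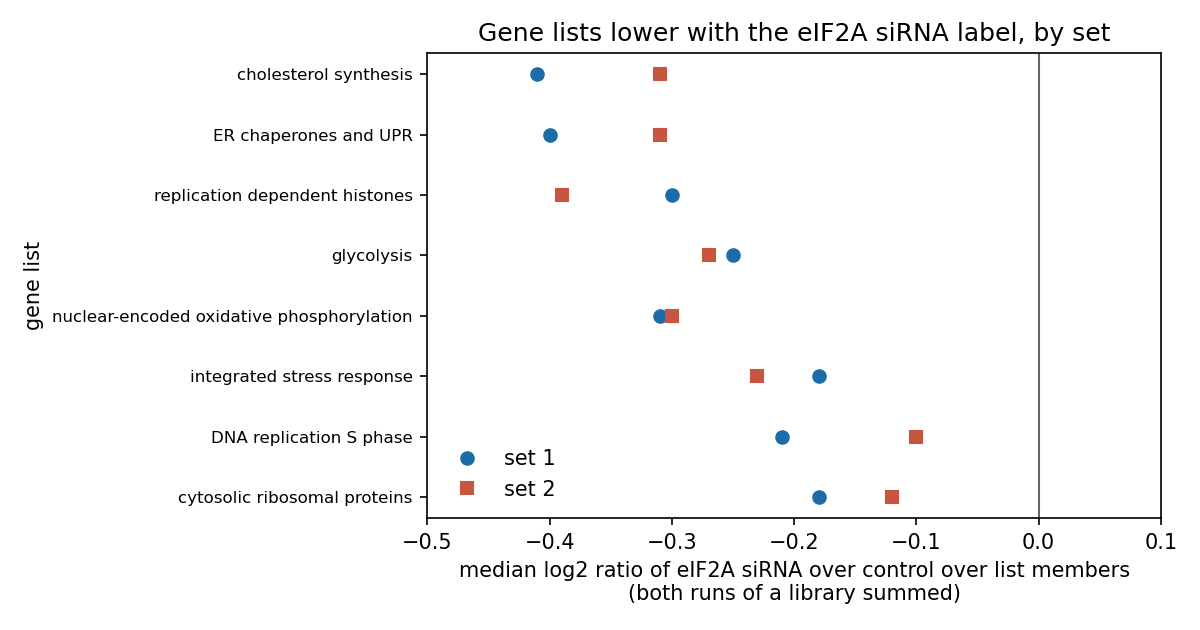
Median log2 ratio of the library labelled eIF2A siRNA over control across the members of each list (horizontal axis), for the 8 lists (vertical axis) that stood lower in the CBP80-labelled comparison, with both runs of a library summed; circles are set 1 and squares set 2. All 16 medians lie below 0, from -0.41 for cholesterol synthesis in set 1 to -0.1 for DNA replication in set 2. The lists were chosen as lower from these same libraries, so the medians are no independent check across sets.

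The other 15 lists had camera adjusted p from 0.0813 to 0.897 in the CBP80-labelled comparison. Among factors of nonsense-mediated decay and the exon junction complex, 3 of 17 rose and none fell, with SMG1 up by 0.71 and SMG5 by 0.53 (camera adjusted p = 0.0813 for the list). Of immediate early genes, ATF3 and EGR1 fell, the latter by 0.53. GDF15, at 6.24 CPM in control, rose by 1.19 among p53 targets, and SLC7A11 fell and FTL rose among oxidative and metal stress genes. Of cadherin, integrin and matrix genes COL4A6 fell by 0.65. Cap-binding and initiation factors, heat shock proteins, mitosis genes and other translation factors with 5' terminal oligopyrimidine tracts had no member past the threshold in this fit, where EIF2B3 was at -0.42, AHSA1 at -0.48, UBE2C at -0.43 and TPT1 at 0.37. Markers of other cell types gave single changes, PODXL at -0.52 among pluripotency genes, CXCR4 at -0.7 among endoderm markers and TAGLN, at 1.16 CPM in control, at 1.76 among fibroblast markers. None changed among mesoderm, ectoderm, and trophoblast and amnion markers.

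With each HEK293T library counted once, 12 of 23 lists were called, the 8 above and 4 more. Cap-binding and initiation factors stood lower with 3 of 36 fallen, EIF2B3 (-0.42), EIF3K (-0.42) and EIF2B2 (-0.4). Immediate early genes stood lower with 3 of 29 fallen, and cadherin, integrin and matrix genes with 4 of 26 fallen and 1 risen, while factors of nonsense-mediated decay and the exon junction complex stood higher with 4 of 17 risen. Adjusted over the list alone, none of the cap-binding factors fell, 3 immediate early genes and 5 cadherin, integrin and matrix genes fell, 1 of the latter rose, and 5 decay factors rose. The camera adjusted p was 0.0293 for immediate early genes and 0.0498 for the other 3, and with an estimated correlation adjusted p = 0.708 for the decay factors, 0.751 for the cap-binding and immediate early lists and 0.868 for the matrix list. None of the 12 lists was called with an estimated correlation, where the smallest adjusted p was 0.608, and 7 lists were called without the set 2 control and 7 with a mean count of at least 50. In lists that were not called, the co-chaperone AHSA1 (-0.48) and the small heat shock protein HSPB1 (-0.54) fell and HSF1, the transcription factor of the heat shock response, rose by 0.48. UBE2C, a ubiquitin-conjugating enzyme of mitosis, fell by 0.41, and the translation factors EEF1D and EIF3H fell by 0.43 and 0.41.

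The eIF4E-labelled runs of the same libraries gave 397 changed genes of 11778, 150 higher and 247 lower with the eIF2A siRNA label, 256 of them shared with the CBP80-labelled runs in the same direction, where independent lists would share 16.9. Since the runs of a pair could hardly be told apart over all genes, the overlap is no second sample of the effect. TSC22D3 (-1.08 ± 0.14), SUMF2 (-1.08 ± 0.17), MYDGF (-1.05 ± 0.13) and PIGL (-1.04 ± 0.14) were again among the 12 largest falls, joined by MICOS13 (-1.05), AIG1 (-1.05) and DPAGT1 (-0.98), the enzyme that starts N-glycan synthesis. RHOT1, a mitochondrial GTPase, had the largest rise (1.16 ± 0.18, edgeR adjusted p = 0.0056), before NETO2 (0.97), DMPK (0.97) and ATN1 (0.97). 10 lists were called, 9 lower and the nonsense-mediated decay list higher (camera adjusted p = 0.0268, and adjusted p = 0.307 with an estimated correlation). No list was called with an estimated correlation in this comparison, where the smallest adjusted p was 0.184. The changes of the CBP80-labelled and eIF4E-labelled runs correlated at r = 0.714 over 11778 genes, which describes 2 runs of the same 4 libraries. The count was 0 without the eIF4E-labelled control of set 2, 36 without that of set 1, 26 without the eIF2A siRNA library of set 1, and 1071 when only these 4 libraries were fitted. It was 189 with library sizes alone, 95 higher and 94 lower.

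Whether translation of CBP80-bound mRNAs responds to the knockdown differently from that of eIF4E-bound mRNAs could not be read from these files, because the libraries under both labels were nearly alike over all genes. The test of that difference called 0 of 11778 genes in edgeR and 0 in DESeq2, with 97 and 10 genes at an unadjusted p under 0.05. In edgeR this is 0.824% of genes, and 0.925 and 0.781% between the IP labels below, far fewer than p-values without any difference would give. The fit's error held the spread between sets, which exceeds that within a pair. It could therefore hardly call a gene here, and few calls are no evidence of no difference. The genes with the smallest p were GSR, with a difference of 0.6 ± 0.22, NRP2 (-0.56 ± 0.21) and TRMT61B (-0.6 ± 0.23), all at an edgeR adjusted p of 1. Between CBP80 IP and eIF4E IP in control siRNA, 0 genes passed in edgeR and 0 in DESeq2, with 109 and 12 genes at an unadjusted p under 0.05. STAU2, a double-stranded RNA-binding protein, was at 0.42 ± 0.14 and TUSC3, a subunit of the oligosaccharyltransferase, at -0.62 ± 0.22, both at an edgeR adjusted p of 1. With the eIF2A siRNA label, 1 gene passed in edgeR, the olfactory receptor gene OR4K15 (edgeR adjusted p = 0.0149), at a mean of 2.09 CPM and named after its value was seen, with 92 genes at an unadjusted p under 0.05, and 0 passed in DESeq2, with 11. TUSC3 was at -0.88 ± 0.21 and MARS2, the mitochondrial methionyl-tRNA synthetase, at 0.38 ± 0.14 there, both at an edgeR adjusted p of 1. No list was called in these 3 comparisons, with smallest camera adjusted p of 0.969, 0.944 and 0.263. Leaving out 1 library called lists in most of these fits, but it leaves the IP labels with unequal shares of the sets. Differences between sets then enter the contrast. In control siRNA the called lists were all higher without the CBP80-labelled library of set 1 and all lower without that of set 2. Such calls cannot be read as a difference between the IP labels. With each pair of runs as a block, the fits of 4 libraries called 2 genes in control siRNA and 4 with the eIF2A siRNA label, all lower with CBP80 labels. In these fits 545 of 11439 and 594 of 11542 genes had an unadjusted edgeR p under 0.05, in that order. That is about as many as p-values without any difference would give, unlike in the fit of 8 libraries.

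In H9, no gene passed the test between libraries labelled eIF2A shRNA and control shRNA. Of 9751 genes, 0 passed in edgeR and 0 in DESeq2, with 91 and 0 at an unadjusted p under 0.05. Those 91 genes are 0.933% of the tested ones, far fewer than p-values without any difference would give. The fit's error held the spread between sets, so it could hardly call a gene between near-identical libraries. The genes of smallest p were GGCT (-0.64 ± 0.22), HMGXB4 (-0.68 ± 0.24), TOM1L1 (-0.52 ± 0.18), MCPH1 (0.78 ± 0.28) and NAT14 (0.74 ± 0.28), all at an edgeR adjusted p of 1. NCBP1 was at 0.03 ± 0.15, HSPA5 at 0 ± 0.21, ATF4 at -0.21 ± 0.39, SRC at 0.07 ± 0.28 and EIF4E at -0.63 ± 0.41, all at an edgeR adjusted p of 1. None of the 20 lists tested was called, pluripotency and ectoderm markers included, and the smallest camera adjusted p was 0.889. Leaving out 1 of the 4 libraries sets a label with 1 set against a label with both, so the difference between sets enters. Lists called in such fits cannot be read as a change with the shRNA label. Markers of endoderm, mesoderm, and trophoblast and amnion had fewer than 3 tested members and were not tested in H9. Within each set these labels mark libraries that lay at 1.04 and 1.07 per degree of freedom, so the comparison sets the members of 2 near-identical pairs against each other. The HEK293T changes in the CBP80-labelled libraries correlated with the H9 changes at r = 0.0122 over 9182 genes.

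The H9 libraries differed instead between set 1 and set 2, which the labels give no condition. The near-identical libraries of a set were summed and each set was taken as 1 sample, so the difference has no replicate check and no test. Among genes with a mean of at least 50 CPM, a rule set after the data were seen, NES, an intermediate filament protein of neural progenitors, was higher in set 2 by a ratio of 2.34 (95% interval for counting error 2.2 to 2.49), and CCND1, a G1 cyclin, by 2.64 (2.21 to 3.18). The largest ratios were VGF at 2.72, CCND1, ANLN at 2.6 and NES. DENR, a translation reinitiation factor, was lower in set 2 with a ratio of 0.276 (0.208 to 0.362), followed by the glycosyltransferase GALNT7 at 0.315, the mitochondrial transcription factor TFAM at 0.388, TSNAX at 0.408 and RPA1, a single-stranded DNA-binding protein, at 0.415 (0.374 to 0.461). SOX11 was at 0.476 (0.403 to 0.561) and EIF2A at 0.595 (0.49 to 0.719). Cytosolic ribosomal proteins lay lower in set 2, with a median log2 ratio of -0.24 and 55 of 65 members lower, below all of 10000 random lists matched on expression. These percentiles describe the 2 sets and leave out correlation between genes. Cadherin, integrin and matrix genes lay higher, with a median of 0.27 and 22 of 25 members higher, above all of those lists. Fibroblast and stromal markers, a list of another cell type that shares no gene with the matrix list, had the largest median of the 20 lists, 0.36, with 8 of 10 members higher (percentile 100). ER chaperones had a median of 0.21 (percentile 99.5), p53 targets 0.34 (99.9), mitosis genes 0.14 (98.7), histones -0.17 (0), cholesterol synthesis -0.18 (0.13) and nuclear-encoded oxidative phosphorylation -0.08 (0.19). Pluripotency genes were at -0.03 (22.6).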

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

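The tests in this part were chosen after the results were seen, except the test of induction by the siRNA over liver genes not looked at before, while the heterogeneity test over those genes was written before its result for RNA of liver-type cells and widened to any outside source afterwards.

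The change of EIF2A with the eIF2A siRNA label differed between the sets of HEK293T, in both runs of each library. Scaled by total coding reads, it was 0.205 on the log2 scale in set 1 and -0.838 in set 2. With TMM scaling and the set 2 library labelled eIF2A siRNA left out, it was 0.06. EIF2A in set 1 was therefore not lower, while a rise depends on the scaling. The difference between the sets was not tested, since each set holds 1 library per siRNA. An exchange of the control and eIF2A siRNA labels within set 1 is argued against, because the set 1 control matched the set 2 control in EIF2A, with a ratio of 0.997 (lower bound 0.907), where a knockdown library would lie lower. Counting error is argued against by the ratio of 2.06 (lower bound 1.85) between the libraries labelled eIF2A siRNA. That the set 1 library came from cells in which the siRNA had not worked cannot be told apart from a real knockdown that footprints on EIF2A do not show: the changes of other genes in set 1 and set 2 correlated at r = 0.77, which alone would argue against it, but both libraries also hold a larger share of reads outside coding sequences, a condition added after r was seen.

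A second pattern lies in reads that the comparisons do not use. In both sets the share of uniquely placed reads outside coding sequences was above control in the library labelled eIF2A siRNA, at 51% against 40% in set 1 and 42.3% against 35.2% in set 2. Where in the genome these reads lie was not analysed here.

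In HEK293T the chi-square per degree of freedom reached at most 1.03 in the 4 pairs of CBP80 and eIF4E labels. Over all genes together, that is near what 1 library sequenced or deposited under both labels would give. TUSC3 nonetheless averaged 24.4 CPM with CBP80 and 45.3 CPM with eIF4E labels in eIF2A siRNA, and the reason was not tested. Separately made libraries that happen to be alike stay open: the closest libraries of 1 group from different sets lay at 3.95, but sets may differ in more than library making, and the labels name no separately made libraries of 1 lysate. In H9 the larger value was 1.07, above sampling noise (chi-square p = 5.88e-07), so whether a single library stands under both shRNA labels stays open too. An exchange of the set number and the shRNA label in H9 would make the sets the knockdown and its control, and EIF2A was lower in set 2 by a ratio of 0.595 (upper bound 0.719), but 2275 of 7386 genes (30.8%) also had an interval between the sets that excludes 1, so EIF2A says little and the exchange stays open; in HEK293T an exchange of set number and IP label stays open, since sets differing by up to 5.52 would follow from 2 cultures as well as from 2 IPs.

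Transcripts of secreted liver proteins appeared in the HEK293T set 1 libraries, with APOB at 37.7 CPM in control and 140.5 CPM in the library labelled eIF2A siRNA against 5.58 and 8.17 CPM in set 2, and ALB at 19 and 65.7 against 4.95 and 5.3 CPM. The test of induction by the siRNA written before its result used 22 genes of a list not looked at before, in which the set 1 control lay at 1.99 times the set 2 control (1.17 to 3.49), and its bound of 1.5 left it open; over the same genes the library labelled eIF2A siRNA lay at 1.79 times control in set 2 (1.04 to 3.16), so induction stays open. RNA from 1 outside source in both set 1 libraries would give 1 ratio for all genes, and over the 9 of those further genes with at least 10 reads in set 1 the ratio was 4.32 (3.03 to 6.29) with a heterogeneity chi-square of 1.11 per degree of freedom (p = 0.353), consistent with such a source. Human liver-type cells as that source stay open: of the fibrinogen chains, which liver cells make together, FGB lay at 0.0707 of FGA (7 against 99 counts, upper bound 0.151) but FGG at 0.384 (38 counts, 0.257 to 0.563), and TTR had 0 counts in set 1. In set 2, 11 of the 41 listed genes lay at 1 CPM or more, and reads from another organism were not tested.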

How the results depend on the processing

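The fit with each library counted once, with all its alternatives, and the blocked fits of 4 libraries were added after the data were seen. Of 265 alternatives to the 20 main values, 196 kept direction and side of the threshold or a count within 1.5 times, and 69 did not. The 196 include counts of 0 that stayed 0 for the difference, between IP labels in control siRNA and in H9. Those fits could hardly call a gene, so the 196 do not measure how firm the results are. EIF2A changed direction, as given below. Genes named past the threshold were chosen for large changes between groups that do not overlap, and lists for being called. By that choice they could hardly change direction. None of the 24 genes named as rises and falls in each eIF2A siRNA comparison and none of its called lists did under any alternative run: of 336 values of the 24 named genes with CBP80 labels 44 missed the threshold, 39 of them with a library left out, of 335 with eIF4E labels 52, and of 288 with each library counted once 9. Lists missed it in 15 of 96, 26 of 120 and 46 of 144 values, in that order. The cause was not tested, except that leaving out a library or fitting fewer libraries changes the residual degrees of freedom by construction. A library left out also makes the shares of the sets unequal between the labels.

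Below, values are given for CBP80 labels, for eIF4E labels and for each library counted once, in that order. Changed genes numbered 291, 189 and 979 with library sizes only, where the share of higher calls was 54, 50.3 and 72% against 39.3, 37.8 and 49.3%. Fits of 4 libraries gave 852 and 1071 for the first 2. With each library counted once, no filter gave 633 and DESeq2 682 genes, and a mean count of at least 50 gave 7 lists. Camera with an estimated correlation called 0, 0 and 0 lists, and fry 4, 3 and 0. With CBP80 against eIF4E labels in eIF2A siRNA, the single gene became 0 with a mean count of at least 50, in DESeq2 and in the fit of 4 libraries. With a mean count of at least 50 the effect correlations were -0.00457 with H9 and 0.866 between the labels.

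The replicate block, taking the set number as a term, gave 2941, 2776 and 3023 changed genes. Deviations from the group means correlated at 0.433 to 0.461 between control and eIF2A siRNA libraries of 1 set, but with only 2 numbers these are not taken as pairing. In fits of 4 libraries the block gave 2 genes between the IP labels in control siRNA and 4 in eIF2A siRNA. In the fits of 8 HEK293T and 4 H9 libraries it changed no call between IP labels or shRNA labels.

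Leaving out each library in turn assumed that the lone library of a group varies like the others. It also left the compared labels with unequal shares of the sets, so differences between sets entered each contrast. Changed genes then ranged from 3 (without control, set 2) to 733 (without eIF2A siRNA, set 2), from 0 to 581 and from 78 to 2129, with the same libraries at the ends. Between IP labels they were 0 in control siRNA and 0 to 3 in eIF2A siRNA, for the difference 0 and in H9 0. Called lists ranged from 8 to 11, 7 to 9 and 7 to 11, from 0 to 4 for the difference, 2 to 4 and 2 to 5 between IP labels in control and eIF2A siRNA, and 2 to 3 in H9. EIF2A ranged from -0.89 to 0.07, -0.86 to 0.08 and -0.88 to 0.06, lowest without the library labelled eIF2A siRNA, set 1, where the last reached edgeR adjusted p = 0.00023, and positive without that of set 2. In H9 it ranged from -0.25 (without eIF2A shRNA, set 1) to 0.59, and was -0.16 without control, set 2. The effect correlations ranged from -0.00077 to 0.0194 with H9 and from 0.498 to 0.693 between the labels. Depth limits H9 most, where 3 counts stand for up to 3.2 CPM.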

Other observations

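The test in this part was written after 4 genes of the pathway had been seen among the largest falls, and before its other members were looked at.

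4 genes named among the falls, DPM2, DPM3, PIGL and DPAGT1, act in the making of dolichol-linked sugars or GPI anchors on the ER membrane. The hypothesis that this pathway stood lower as a group with the eIF2A siRNA label was tested on 39 members not looked at before. With each library counted once, 6 of them fell and none rose in edgeR, with a median log2 change of -0.19 and 28 below 0. They included PIGH (-1.07 ± 0.23, edgeR adjusted p = 0.00092), PIGP (-0.58 ± 0.2), GPAA1 (-0.54 ± 0.17), PIGO (-0.46 ± 0.14) and ALG8 (-0.45 ± 0.14). Camera gave p = 0.0023 at the preset correlation and p = 0.16 with an estimated correlation of 0.044. Over all genes of this fit, 1492 of 12331 passed, 756 of them lower. The pathway thus stood lower than other genes at the preset correlation only, and whether it moves with the label stays open. The libraries labelled eIF2A siRNA also differ from control in their share of reads outside coding sequences. A trend with coding length was not tested, since no coding lengths were used here.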
